A study of Homo sapiens with 6 samples.

How the data were processed

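SKNBE2 cells, a human neuroblastoma line with amplified MYCN, were left untreated (Control) or treated with DFMO (difluoromethylornithine), an inhibitor of ornithine decarboxylase, at 250 µM for 4 days. Each group had 3 libraries. Nothing in the labels says whether the 3 replicates of a group were separate cultures, so the spread between them may be technical only. Per the labels, stranded mRNA libraries were sequenced on an Illumina NovaSeq with single reads of 100 nt, and the genome build was GRCh38. The aligner and the quantifier are not given in the sources used here.

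The deposited table held, for each library, a percent for each splicing event, and this percent was the authors' unit for the inclusion of an exon, the retention of an intron or the use of a splice site. Beside each percent, the deposited table held a quality text, and other text columns gave the length of the alternative sequence and its coordinates. The quality text carried a coverage score and the reads assigned to inclusion and to exclusion. All percents were recomputed from these reads, and 100% of them lay within 0.5 points. Inclusion reads need not be whole numbers, as with 5.25 of 7 for a PAOX exon at 75% in DFMO replicate 1. They thus seem to be the total reads split by the percent, and the agreement is no independent check. The table listed 721551 events, of which 1340 had no gene symbol, and every column with values per library was used. Event reads per library, summed over the entries of all classes so that a read can count more than once, ran from 77648922 to 103250467. In every pair of libraries of the same group, exon reads varied by 2.33 to 2.54 times the variance of counting alone, so intervals that cover counting error only would be too narrow.

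Events entered a test when each library had a coverage score of LOW or better and at least 10 reads, and the mean percent over the 6 libraries lay between 5 and 95. The log2 odds of inclusion, with 0.5 added to both read numbers, were fitted with limma 3.58.1 in R 4.3.3. Its empirical Bayes step was robust and had a trend of the variance on the expected counting variance. P values were two-sided and adjusted by Benjamini-Hochberg within each of the 4 event classes. An event was called when its adjusted p was below 0.05 and the group means differed by at least 10 points. For introns, acceptors and donors, limma gave infinite prior degrees of freedom at the median, so their variances followed the trend alone and very small p values rest on that trend. For exons, the median was 10.1. Without the trend, the medians were 2.25 for exons and 2.65 to 3.06 for the other classes. Acceptor and donor sites of the same event share their reads, so events with a called site were counted too.

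Mean retention and mean microexon inclusion per library were compared with exact permutation tests, two-sided, for which 0.1 is the smallest p that 3 libraries against 3 can give. Microexons were exons of 3 to 27 nt. Frame and list membership were tested with Fisher's exact test, two-sided. Because the series holds no gene counts, a junction-read proxy of gene expression was computed. It was the mean, over the exon events of a gene with a score of LOW or better in every library, of log2 of 1 plus the event's reads, after scaling each library to 1e+06 event reads. Exon totals count both junctions of an included exon, so the proxy also moves with inclusion. The proxy was fitted with limma with a mean-variance trend, and a gene was called at an adjusted p below 0.05 and a change of at least 1.5-fold. In accounts of gene lists, a gene rose or fell at an adjusted p below 0.05, whatever its size. Lists were tested with camera from limma with a preset correlation of 0.01, and with an estimated correlation beside it.

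The 18 gene lists covered polyamine metabolism, eIF5A hypusination and translation initiation, SR proteins and related regulators, hnRNPs and other splicing regulators, the core spliceosome, detained-intron genes, neural microexon genes, noradrenergic and mesenchymal neuroblastoma identity, MYC targets, cytosolic ribosomal proteins, mitochondrial respiration and translation, the cell cycle, DNA repair, apoptosis, chromatin modifiers, neurite and cytoskeleton, and synapse and vesicle release. The groups, the filters, the tests, the lists, the alternative settings (save those named as added) and the rule for named genes were fixed before the data were examined. The rule names the called events whose groups do not overlap, by size and with 1 event per gene. It takes 7 exons, 5 introns in each direction and 3 acceptors and 3 donors. It adds up to 4 called events per list, any tested event of SAT1, ODC1, AMD1, AZIN1, SMS, SRM, OAZ1 and PAOX, the 5 highest and 5 lowest proxy differences among called genes, and each measured gene of the polyamine list. Examples from the lists of the proxy and the exon and intron of SAT1 that were not tested were picked after their values were seen. Some gene names that the rule covers are left out of the text. Also picked after values were seen were 3 further lists, of sterol synthesis and uptake, NRF2 targets and ATF4 targets. Their p values were adjusted over these 3 lists alone, apart from the 18 lists.

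Coordinates came from the deposited table and were compared with GENCODE release 29. Exact matches were found for 77.7% of exons with reads, 100% of introns, 38.4% of acceptors and 34.2% of donors. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

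The tests were tried on simulated reads with the depths of these libraries and 100 changed events per size. Replicate noise was set to the same level for all events, and likewise for all genes of the proxy. Noise that differs between events was not simulated, so the false calls below do not test the variance trend. Of changes of 20 points, limma called 38% in exons, 56% in introns, 35% in acceptors and 32% in donors. Of changes of 10 points, it called 2% to 5%. It made 0 false calls in exons, 1 in introns, 1 in acceptors and 2 in donors. A quasi-binomial test called 61%, 73%, 55% and 57% of the changes of 20 points, with 3, 4, 2 and 7 false calls. For the proxy, 90% of 2-fold and 11% of 1.5-fold changes were called, with 0 false calls. camera called 2 of 2 changed lists and 0 of 20 random lists.

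The alternatives for events were a replicate block, each library left out in turn, offsets of 1 and 0.1, at least 20 reads, a score of OK or better, no filter on the mean percent, thresholds of 15 points and of none, the percent scale, the quasi-binomial test, no variance trend, a rule without a test, and, for introns, balanced reads at both ends. Those for the proxy were a replicate block, left-out libraries, median-of-ratios scaling, pseudocounts of 0.1 and 5, low genes left out, the event with the most reads and no size threshold. Covariates for tested sites and reads per gene in the list tests, and intron events in place of exon events in the proxy, were added after the data had been seen.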

Results

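The data were percents of alternative splicing in SKNBE2 cells, a human neuroblastoma line with amplified MYCN, with and without DFMO, a drug that blocks ornithine decarboxylase and so the first step of polyamine synthesis. The comparison asked how RNA processing in this line differs with the drug; polyamine levels were not part of the data. There were 3 Control libraries and 3 libraries from cells held at 250 µM DFMO for 4 days. For each library the deposited table gave the percent of reads that include an exon, retain an intron or use a splice site, over 223565 exon, 192965 intron, 171733 acceptor and 133288 donor entries. Event reads came to 84964542, 77648922 and 103250467 in Control replicates 1, 2 and 3 and to 100005273, 82918379 and 86167448 in DFMO replicates 1, 2 and 3. The first principal component of the exon log odds held 33.6% of the variance and parted the 3 Control from the 3 DFMO libraries. Errors below are SD with n = 3 per group unless an SE is named, adjusted p values are from limma, and coordinates are GRCh38.

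Genes that set polyamine levels moved in both directions with DFMO. The junction-read proxy of AMD1, whose product supplies the aminopropyl groups of spermidine and spermine, rose 3.68-fold, from 4.30 ± 0.08 to 6.18 ± 0.03 on the log2 scale (adjusted p = 1.5e-07). AZIN1, the antizyme inhibitor that shields ornithine decarboxylase, rose 1.58-fold (log2 0.66, SE 0.04, adjusted p = 1.4e-05). OAZ1 and OAZ2, the antizymes that send ornithine decarboxylase to the proteasome, fell by 1.02 and 0.85 on the log2 scale (SE 0.02 and 0.04; adjusted p = 1.5e-07 and 3.8e-06). The proxy of ODC1, the drug's target, was 6.17 ± 0.02 in Control and 5.98 ± 0.02 with DFMO, which passed the adjusted p (4.0e-04) but not the 1.5-fold minimum. SRM, the spermidine synthase, had 5.68 and 5.70 (adjusted p = 0.621).

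Of the 22 measured genes of the polyamine list, 4 rose, 6 fell and 12 did not pass the test, and the counts adjusted over the list alone were 4 and 6. Besides the genes above, ADI1 (log2 0.17) and AHCY (0.15) rose, and MRI1 (-0.24), ENOPH1 (-0.24) and MAT2B (-0.22) fell, all of them in the methionine cycle or its salvage branch and all under 1.5-fold. The members that did not pass were ATP13A2 (0.12), SAT2 (0.08), SLC3A2 (0.07), MTAP (0.05), MAT2A (0.03), SRM (0.02), SLC18B1 (0.02), GPC1 (-0.01), APIP (-0.03), ATP13A3 (-0.09), ARG2 (-0.11) and SLC12A8 (-0.19). The list as a whole had no direction (camera adjusted p = 0.741, and adjusted p = 0.776 with an estimated correlation). The AMD1 value rests on 1 exon event; over its 4 intron events, a setting chosen after the data had been seen, the log2 difference was 1.89.

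**Figure D1:**
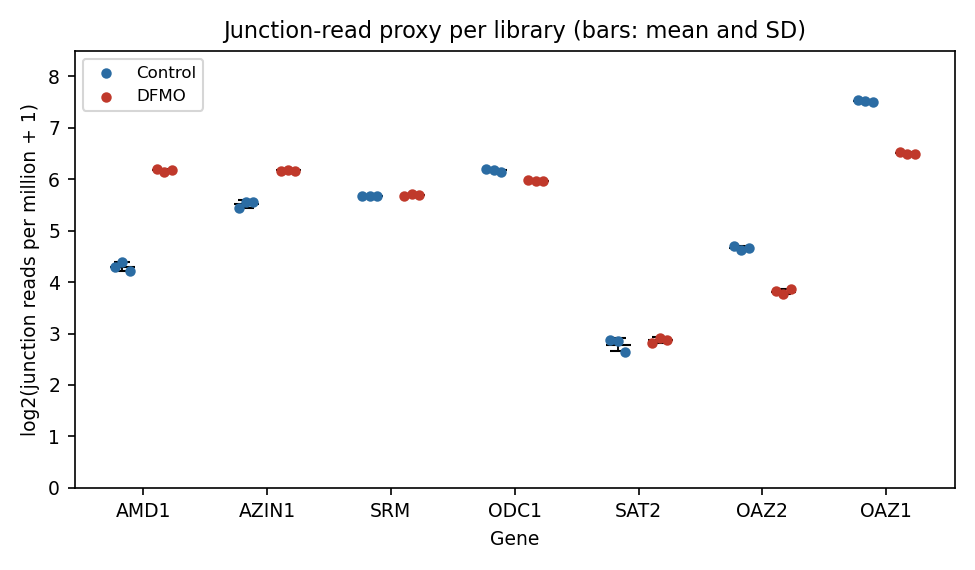
Junction-read proxy (log2 of reads per event and library, scaled to library size, plus 1) of polyamine genes in each library; points are the 3 Control (blue) and 3 DFMO (red) libraries, and bars are the mean and SD. AMD1 lies at 4.30 in Control and 6.18 with DFMO, and OAZ1 at 7.53 and 6.51.

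Splicing of polyamine genes changed at a few sites. A 90-nt coding exon of ATP13A3, a transporter of the polyamine-carrying ATPase family (chromosome 3, 194412199 to 194412288), rose from 72.9% ± 6.09 to 86.0% ± 2.45 (adjusted p = 0.0132), and retention of a 9349-nt intron of SLC3A2, an amino acid and polyamine transport subunit, rose from 28.8% ± 1.58 to 39.9% ± 2.35 (adjusted p = 2.08e-03). A 146-nt exon in the 5′ UTR of AZIN1 (chromosome 8, 102849999 to 102850144) had 33.4% ± 2.78 in Control and 26.6% ± 1.84 with DFMO, which passed the adjusted p (0.0256) but fell short of 10 points, and a pair of AZIN1 acceptors in another part of the gene differed by 0.74 points (adjusted p = 0.836). SAT1 encodes the acetyltransferase that marks spermidine and spermine for export. Its 110-nt exon (chromosome X, 23784294 to 23784403, in a transcript without coding sequence) had 2.05% ± 2.83 in Control and 40.8% ± 16.1 with DFMO, without overlap (exact permutation p = 0.1, the smallest possible). Retention of the 1444-nt SAT1 intron around it was 3.13% ± 1.34 and 24.2% ± 9.54 (exact permutation p = 0.1). The SAT1 exon had 57, 70 and 82 reads in Control and 20, 7 and 11 with DFMO, under the coverage filter, so SAT1 was not tested with limma and both values are imprecise. ODC1, AMD1, SMS, SRM, OAZ1 and PAOX had no event that passed the filters. Of the 31 tested sites of the list, 2 were called, and 2 when adjusted over the list alone. The ATP13A3 call ended on the percent scale and without Control replicate 3 or DFMO replicate 1 (10.2 and 11.8 points) and the SLC3A2 call without DFMO replicate 3 (9.79 points).

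**Figure D2:**
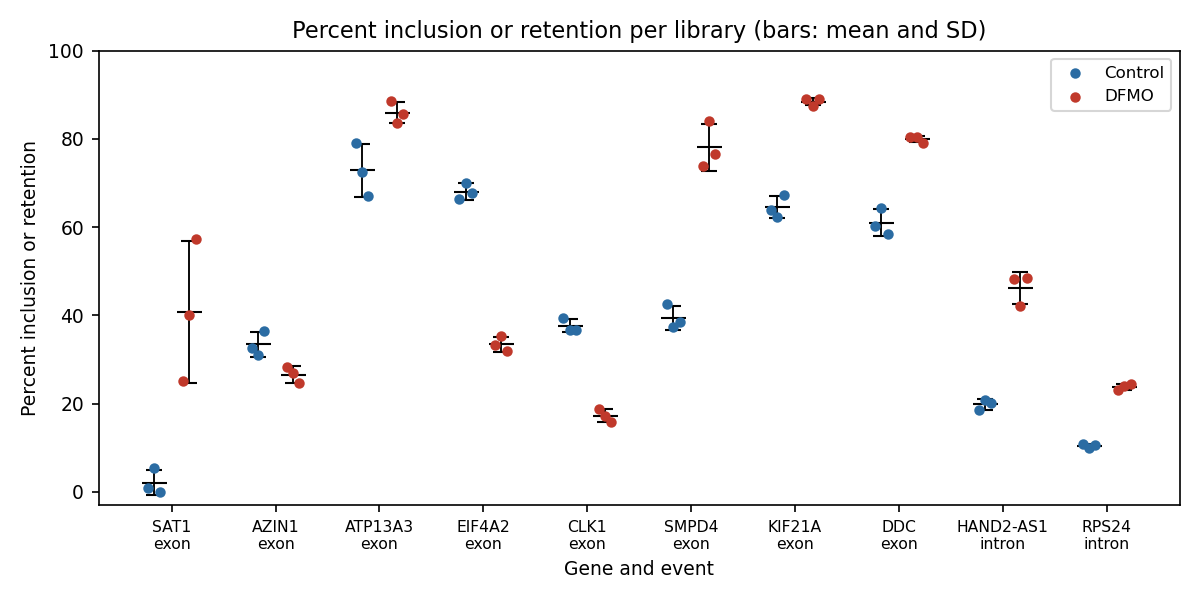
Percent inclusion (exons) or retention (introns) in each library for 10 events of named genes; points are the 3 Control (blue) and 3 DFMO (red) libraries, and bars are the mean and SD. The EIF4A2 exon goes from 68.1% to 33.4% and the KIF21A exon from 64.5% to 88.5%; the SAT1 exon has at most 20 reads in a DFMO library.

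Called cassette exons mostly rose in inclusion. Of 7500 tested exons in 4145 genes, 203 were called higher and 56 lower with DFMO, in 228 genes, with a median size of 16.2 points. Over all tested exons, 60.3% were higher, and the median difference was 1.24 points. The called changes included a coding exon of SMPD4, a sphingomyelinase (87 nt, chromosome 2, 130161186 to 130161272), which rose from 39.4% ± 2.77 to 78.1% ± 5.34 (adjusted p = 9.7e-05), and an exon of EIF4A2, a helicase of translation initiation (111 nt, chromosome 3, 186788310 to 186788420), which fell from 68.1% ± 1.91 to 33.4% ± 1.75 (adjusted p = 3.3e-08). The EIF4A2 exon is annotated in a transcript without coding sequence. An exon of DIS3, a ribonuclease of the exosome (158 nt, chromosome 13, 72780846 to 72781003), fell from 81.8% ± 1.92 to 54.1% ± 2.56 (adjusted p = 1.1e-04).

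Other exons with the largest rises lay in TANGO2 (35.8% to 78.3%), DTNB, a dystrobrevin of the dystrophin complex (14.6% to 56.2%), DDHD1, a phospholipase (20.03% to 57.0%), CAMK2G, a calcium-dependent kinase (16.1% to 50.7%), and FNIP2, a folliculin partner (19.5% to 52.7%). The largest difference was in an 8-nt exon of FLOT1, a membrane scaffold gene, with 8.27% ± 14.3 and 67.5% ± 8.16 (adjusted p = 0.0285). The FLOT1 and DDHD1 exons are not annotated. Besides EIF4A2 and DIS3, the 7 largest falls included those in RNFT1 (88.0% to 55.1%), LINC01128 (73.9% to 47.0%), R3HDM1 (63.1% to 37.2%), FAM122B (47.4% to 23.4%) and FUCA2, a fucosidase (93.0% to 70.1%). The FUCA2 exon is not annotated either. Without the variance trend, limma called 12 exons higher and 2 lower (1295 exons at an unadjusted p below 0.05, against 1543 with the trend) and, of the 69 called events in all 4 classes that the naming rule covers, limma kept DTNB alone. The counts also dropped over 1.5 times without Control replicate 1 (134 higher), Control replicate 3 (132 and 30) and DFMO replicate 1 (128 and 30). The FLOT1 call ended with an offset of 0.1 and without any library but Control replicate 3 (54.6 to 62.3 points). LINC01128 lost it with no filter on the mean percent and without any but DFMO replicate 3 (20.9 to 27.7 points), and R3HDM1 without Control replicate 1 or 3 or DFMO replicate 1 or 2 (21.7 to 27.4 points). FNIP2 lost it without DFMO replicate 1 (29.1 points).

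**Figure D3:**
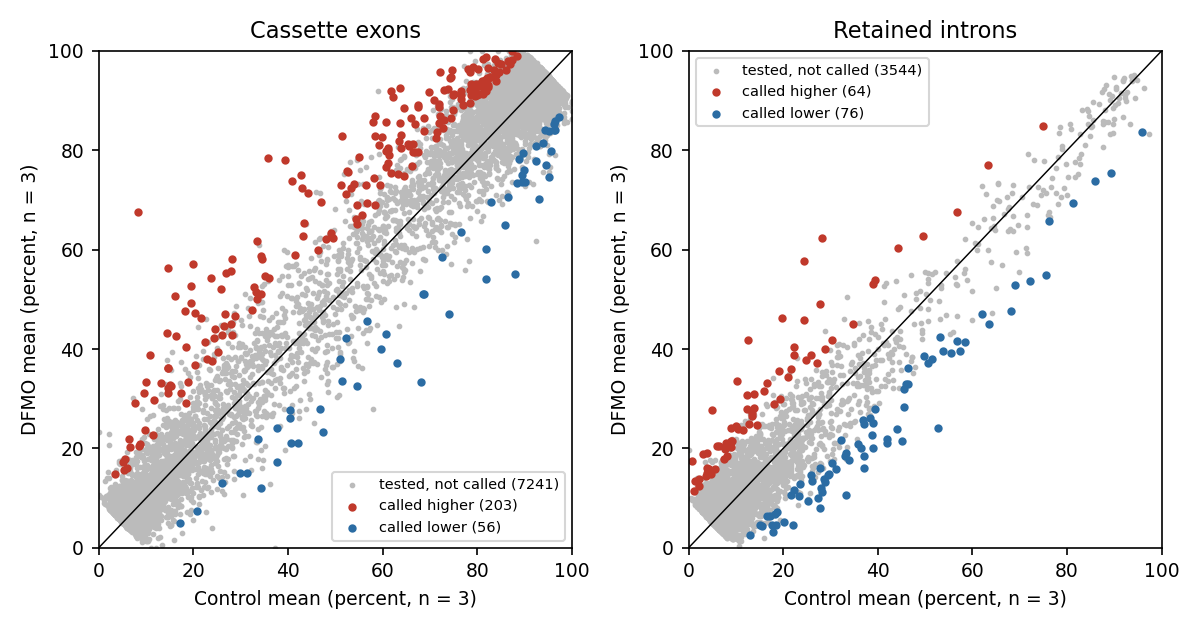
Mean percent in DFMO libraries (y axis, n = 3) against Control libraries (x axis, n = 3) for tested cassette exons (left) and retained introns (right), with the line of equality in black. Called exons lie above the line in 203 cases and below it in 56, and called introns in 64 and 76.

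Some genes for splicing regulators had called events. Among SR proteins and their partners, a 120-nt exon of ACIN1, a splicing-linked scaffold (chromosome 14, 23089982 to 23090101), rose from 19.6% ± 3.23 to 49.2% ± 1.57 (adjusted p = 5.4e-04), and an exon of SRRM3, an activator of neural microexons, from 74.6% to 96.1%. The SRRM3 exon is annotated in a transcript without coding sequence. An exon of the kinase gene DYRK2 rose from 66.0% to 86.5%. A 91-nt coding exon of CLK1, a kinase of SR proteins (chromosome 2, 200860125 to 200860215), fell from 37.6% ± 1.52 to 17.3% ± 1.49 (adjusted p = 1.5e-04). Of the 148 tested sites of this list, 6 were called higher and 1 lower, and 10 were called when adjusted over the list alone. For hnRNPs and other regulators, 3 of 209 sites were called higher and 1 lower, and 4 when adjusted over the list alone. They were a 136-nt HNRNPA2B1 exon annotated in a transcript that undergoes nonsense-mediated decay (54.7% to 69.0%), an HNRNPH3 donor (56.7% to 69.0%) with the competing donor of the same event (41.8% to 29.8%), and an EWSR1 intron (14.6% to 24.7%). In the core spliceosome, 3 of 128 sites were called, all higher, and 3 when adjusted over the list alone. These were exons of DDX42, a helicase (65.6% to 80.9%), and PRPF3, a tri-snRNP protein (11.6% to 22.6%), and an intron of PRPF38B (9.27% to 21.5%). The PRPF3 exon, too, is annotated in a transcript without coding sequence. Detained-intron genes had 3 called of 140 sites (1 higher, 2 lower; 3 when adjusted over the list alone), the EIF4A2 and CLK1 exons and an intron of OGT, the O-GlcNAc transferase (24.9% to 37.7%). None of these 4 lists passed the test for the share of genes with a called event (6 of 38, 3 of 59, 3 of 42 and 3 of 36 genes; Fisher's exact adjusted p = 0.22, 1, 1 and 1). With no size threshold, the SR, hnRNP and detained-intron lists passed (adjusted p = 0.0119, 6.62e-04 and 6.62e-04, the lowest of 3 alternatives each, the highest being 0.688, 1 and 1), and the hnRNP list turned from fewer to more genes. Calls ended without some libraries for DYRK2 (Control replicate 1 or 3, DFMO replicate 1 or 3; 17.4 to 20.9 points), PRPF3 (Control replicate 1 or 2, DFMO replicate 1 or 2; 9.06 to 12 points), EWSR1 (the same 4; 7.68 to 9.87 points), DDX42 (Control replicate 1; 12 points) and OGT (DFMO replicate 2; 10.1 points). EWSR1 and OGT also lost the call on the percent scale, and EWSR1 with no filter on the mean percent.

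Exons of several neuronal genes were included more often with DFMO. In the neural microexon list, 12 of 72 tested genes had a called event, against 389 of 5992 other genes (odds ratio 2.88, Fisher's exact adjusted p = 0.0436). In the list for synapse and vesicle release it was 8 of 42 genes (odds ratio 3.37, adjusted p = 0.0494). A 21-nt exon of KIF21A, a kinesin (chromosome 12, 39330242 to 39330262), rose from 64.5% ± 2.48 to 88.5% ± 0.89 (adjusted p = 5.2e-06). Exons above the 27-nt limit for microexons rose too. They lay in UNC13A, which primes synaptic vesicles (30 nt, 27.9% to 55.7%), and GRIN1, an NMDA receptor subunit (63 nt, 14.6% to 36.2%). In BIN1, which bends membranes, exons of 129 and 72 nt rose (47.1% to 69.5% and 60.8% to 79.8%), the 72-nt exon not being annotated. An acceptor of CACNA2D1, a calcium channel subunit, rose from 67.4% to 88.8%. The microexon list had 11 sites called higher and 4 lower of 313, and 19 called when adjusted over the list alone. The synapse list had 8 higher and 3 lower of 142, and 11 when adjusted over the list alone. Called exons over all genes were also mostly higher (203 of 259), so rises are not particular to these lists. Both list calls ended with tested sites and reads per gene as covariates, an alternative chosen after the data had been seen (adjusted p = 0.193 and 0.176), and with no size threshold (0.221 and 0.136); over 3 alternatives each, adjusted p ran from 0.0391 to 0.221 and from 0.0499 to 0.176. The GRIN1 call ended with no filter on the mean percent and without any of the 6 libraries (16.6 to 24.2 points), and the CACNA2D1 call on the percent scale. The larger BIN1 change lost the call there too and without Control replicate 2 or 3 or DFMO replicate 1 or 3 (19.2 to 22.9 points), the smaller without any but DFMO replicate 1 (15.7 to 20.6 points), and UNC13A without Control replicate 3 (24.6 points).

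In genes of the noradrenergic identity of neuroblastoma cells, the few splicing events that were called were higher with DFMO. A 114-nt exon of DDC, which makes dopamine (chromosome 7, 50539915 to 50540028), rose from 61.0% ± 2.99 to 79.97% ± 0.76 (adjusted p = 5.2e-06), and a 135-nt exon of SLC6A2, the noradrenaline transporter, from 63.2% ± 1.38 to 75.2% ± 0.67 (adjusted p = 1.1e-04). An intron of RET, a receptor kinase gene (39.0% to 53.02%), was retained more. Of 67 tested sites, 6 were called, all higher, and 7 when adjusted over the list alone; 4 of 24 genes had a called event (adjusted p = 0.315). With no size threshold this list passed (adjusted p = 0.0472, the lowest of 3 alternatives, the highest being 0.693). In the neurite list, exons of ANK2, an ankyrin (26.0% to 42.8%), and CTTN, which binds actin (81.7% to 94.0%), rose; they were the 2 called of 118 sites, and 2 when adjusted over the list alone (2 of 37 genes, adjusted p = 1). The ANK2 call ended without DFMO replicate 1 (14.4 points). The mesenchymal list had 0 called of 14 sites and 0 adjusted over the list alone (0 of 5 genes, adjusted p = 1).

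Intron retention changed in both directions. Of 3684 tested introns in 2631 genes, 64 were called higher and 76 lower, in 136 genes. A 45734-nt intron of HAND2-AS1, a noncoding RNA next to a neural crest transcription factor gene (chromosome 4, 173536971 to 173582704), rose from 19.8% ± 1.23 to 46.2% ± 3.60 (adjusted p = 3.8e-25). A 3310-nt intron of RPS24, a protein of the small ribosomal subunit (chromosome 10, 78037305 to 78040614), rose from 10.4% ± 0.46 to 23.8% ± 0.70 (adjusted p = 1.2e-32). A 407-nt 5′ UTR intron of HDAC9, a histone deacetylase (chromosome 7, 18495855 to 18496261), fell from 52.8% ± 4.13 to 24.1% ± 8.08 (adjusted p = 1.7e-05).

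Retention also rose in CEP152, a centriole gene (28.1% to 62.3%), PAXBP1 (24.4% to 57.7%) and TRAF5, an adaptor of TNF receptors (10.2% to 33.6%). It fell in DUS4L, a tRNA-modifying enzyme (45.1% to 21.5%), the noncoding RNAs MINCR (33.3% to 10.7%) and CD27-AS1 (37.0% to 16.1%), and CAMKV (41.8% to 21.1%). Without the variance trend, limma called 0 introns (644 at an unadjusted p below 0.05, against 814 with it), and a quasi-binomial test called 77 higher and 89 lower. On the percent scale 23 and 40 were called, which ended the calls of CEP152 and TRAF5, and with balanced reads at both ends 17 and 27; the counts dropped over 1.5 times without Control replicate 1 (44 lower) and DFMO replicate 1 (41 higher).

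Splice sites moved in fewer genes. Acceptor use changed in 25 of 2008 tested events and donor use in 32 of 1492. A 147-nt acceptor form of ATG2B, a lipid transfer protein of autophagy (chromosome 14, 96305589 to 96305815), fell from 86.7% ± 23.0 to 37.9% ± 6.72 (adjusted p = 0.0136), and an acceptor of SECISBP2, needed to make selenoproteins, rose from 15.5% to 39.3%. A PCNP acceptor rose from 26.8% to 52.9%. A donor of ACE, the angiotensin-converting enzyme (chromosome 17, 63477493 to 63477587), rose from 23.3% ± 6.04 to 54.7% ± 12.4 (adjusted p = 8.18e-03). Donors of RP11-706O15.5 (68.5% to 37.2%) and RBBP8, which trims DNA ends for repair (58.7% to 32.0%), fell. Without the variance trend, limma called 0 acceptor and 0 donor events (396 and 314 sites at an unadjusted p below 0.05, against 511 and 434), the quasi-binomial test called 49 and 53 sites against 47 and 58, and the percent scale called 6 and 7 events and ended the calls of these 6 genes. Counts dropped over 1.5 times without DFMO replicate 1 (8 acceptor events), DFMO replicate 2 (15 acceptor and 20 donor events) and Control replicate 2 (19 donor events). Calls ended in the quasi-binomial test, with an offset of 0.1 and without any of the 3 DFMO replicates for ATG2B (46.8 to 52.8 points), and with no filter on the mean percent for PCNP. They also ended without some libraries for PCNP (Control replicate 2, DFMO replicate 1 or 2; 20.5 to 26.5 points), SECISBP2 (DFMO replicate 1; 21.0 points), ACE (Control replicate 2 or DFMO replicate 2; 28.4 and 24.3 points), RP11-706O15.5 (Control replicate 1 or 2, DFMO replicate 2 or 3; 26.6 to 32.2 points) and RBBP8 (Control replicate 1 or 2, DFMO replicate 1 or 3; 24.3 to 27 points).

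Called events in the other lists were scattered. Among cell cycle genes, retention fell in KIF4A, a mitotic kinesin (27.8% to 8.07%), and CDCA5, a cohesin regulator (29.7% to 14.9%), while a NUF2 donor (53.9% to 71.1%) and a KIF23 exon (33.4% to 50.1%) rose. For DNA repair, a RECQL5 intron fell (72.2% to 53.7%), and introns of POLQ, a polymerase of end joining (1.41% to 13.5%), and NBN, a sensor of breaks (2.11% to 13.9%), and an NBN acceptor (6.40% to 22.7%) rose. Among chromatin genes, retention rose in BPTF, a remodeler subunit (0.76% to 17.6%), and fell in BRPF1 (31.2% to 15.8%), and an ATRX donor fell (22.5% to 5.65%). Among ribosomal protein genes, besides RPS24, an RPL15 donor fell (28.7% to 18.6%) and an RPL26 donor had 71.9% ± 6.71 and 86.7% ± 11.6, called although the groups overlap. A DAP3 donor fell (52.6% to 40.1%) in the apoptosis list, which also held ACIN1, and EIF4A2 was the called gene of the hypusination and translation list.

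Sites called, and sites called when adjusted over the list alone, were 6 and 6 for the cell cycle, 8 and 8 for DNA repair, 9 and 9 for chromatin, 5 and 7 for ribosomal proteins, 3 and 5 for apoptosis, 1 and 1 for hypusination and translation, and 0 and 0 for MYC targets (72 sites) and mitochondria (42 sites). None of these lists, nor the polyamine list with 2 of 10 genes, passed that test against other genes (Fisher's exact adjusted p from 0.497 to 1). With no size threshold the polyamine list passed (adjusted p = 0.0119, the lowest of 3 alternatives, the highest being 0.688). On the percent scale the calls of KIF23, RECQL5, POLQ, NBN, BRPF1, RPL26, RPL15 and ATRX ended. RECQL5, BRPF1 and RPL15 lost it with no filter on the mean percent, KIF23 and RPL26 in the quasi-binomial test, KIF23 and RPL15 with a replicate block, and all of KIF23, RPL15 and RPL26 with an offset of 0.1. Calls ended without any of the 6 libraries for ATRX (12 to 20.4 points) and RPL15 (8.73 to 11.8 points). They ended without 5 libraries for KIF23 (all but DFMO replicate 1; 11.5 to 18.1 points) and DAP3 (all but Control replicate 2; 11.8 to 13.3 points), and without the 3 DFMO replicates for POLQ (11.5 to 12.7 points). For single libraries, they ended for KIF4A (Control replicate 1 or 3, DFMO replicate 1; 15.9 to 20.3 points), RECQL5 (Control replicate 1, DFMO replicate 1 or 3; 13.5 to 17.9 points), BRPF1 (Control replicate 1 or 2, DFMO replicate 1; 12.6 to 15.3 points), the NBN intron (DFMO replicate 2; 8.19 points), the NBN acceptor (DFMO replicate 1; 9.58 points) and RPL26 (DFMO replicate 3; 10.7 points).

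Microexons, a class that neurons include more than other cells, had a mean inclusion of 36.2% ± 0.211 in Control and 38.6% ± 0.369 with DFMO over 225 exons, a difference of 2.39 points without overlap (exact permutation p = 0.1, the smallest possible). Of these microexons, 8 were called higher and 1 lower. The 7275 longer exons had 57.4% ± 0.0335 and 58.9% ± 0.0427, a difference of 1.46 points (exact permutation p = 0.1). The gap between both classes moved by 0.926 points (exact permutation p = 0.1). Mean retention over 88789 introns was 1.15% ± 0.0546 and 1.24% ± 0.0657, a difference of 0.0924 points that did not pass (exact permutation p = 0.2); over introns of 5% to 95% it was 0.297 points (exact permutation p = 0.5), and the median difference was 0. A length that keeps the reading frame was found in 138 of 259 called exons (53.3%) and in 43.0% of the 7241 others (odds ratio 1.51, 95% interval 1.17 to 1.95, Fisher's exact p = 1.38e-03). These counts include exons outside coding sequence. Among coding exons alone, it was 57.8% of 192 called and 49.8% of 4230 others (odds ratio 1.38, 95% interval 1.02 to 1.88, Fisher's exact p = 0.0322).

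Beyond polyamine genes, expression by the junction-read proxy changed over 1.5-fold in few genes. Of 9232 genes, 62 were called higher and 42 lower with DFMO. Besides AMD1, the largest rises were in PHKA2-AS1 (2.15-fold), TRAPPC6A, a vesicle tethering subunit (2.11-fold), C16orf58 (2.06-fold) and SCG5, a chaperone of neuroendocrine granules (2.02-fold). Besides OAZ1, falls over 1.5-fold included NQO1, a quinone reductase, which fell by 1.22 on the log2 scale (SE 0.05, adjusted p = 4.2e-06), DKK1, a Wnt antagonist, which fell by 1.05, and CRABP2, a retinoic acid carrier, which fell by 0.91. At an adjusted p below 0.05, without the size threshold, 2080 genes were higher and 2032 lower. The called counts were 178 and 126 with a pseudocount of 0.1, 10 and 8 with 5 (PHKA2-AS1 was no longer called, log2 0.51), and 98 and 80 from the event with the most reads. Over intron events, a setting chosen after the data had been seen, 98 of the 99 called genes measured by both had the same direction and 67 were called by both. Reads over a spliced junction can count in both kinds of event, so this is no independent check.

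Cell cycle genes fell as a list. Of 73 measured, 52 fell, 7 rose and 14 did not pass (54 and 7 adjusted over the list alone; camera adjusted p = 7.7e-10, and adjusted p = 0.0177 with an estimated correlation). PLK1, a mitotic kinase, fell by 0.60 (SE 0.03), CDC20, an activator of the anaphase complex, fell by 0.60 (SE 0.07) and NCAPG, a condensin subunit, fell by 0.59 (SE 0.04), while CDKN1A, the inhibitor p21, rose by 0.36 (SE 0.09). MYC targets fell too, with 40 of 60 down and 2 up (41 and 2 adjusted over the list alone; adjusted p = 1.3e-08, and adjusted p = 0.0438 with an estimated correlation), among them HSPD1, a mitochondrial chaperone, which fell by 0.37, and NOP16, a nucleolar protein, which fell by 0.33. Of 77 DNA repair genes, 25 fell, such as PRKDC, which fell by 0.31, and 8 rose, such as XRCC1 (0.34); adjusted over the list alone it was 24 and 8 (adjusted p = 0.036, and adjusted p = 0.162 with an estimated correlation). Ribosomal protein genes rose, with 20 of 31 up and 2 down (22 and 2 adjusted over the list alone; adjusted p = 1.2e-06, and adjusted p = 0.259 with an estimated correlation), among them RPL15 (0.53) and RPL8 (0.34), while RPLP0 fell by 0.53. The values of CDC20, HSPD1, RPL15 and RPLP0 rest on 1 exon event each. RPL15 and RPLP0 had low Control means (2.93 and 2.64, against 6.82 for RPL8). Of 38 detained-intron genes, 14 rose, such as EIF4A2 (0.76) and CIRBP (0.44), and 2 fell (14 and 2 adjusted over the list alone; adjusted p = 5.87e-03, and adjusted p = 0.479 with an estimated correlation). Other splits of the 6 libraries gave up to 4 lists with a direction at the preset correlation, against these 5.

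The remaining lists had no direction (camera adjusted p from 0.564 to 0.97, and adjusted p from 0.679 to 0.971 with an estimated correlation). In translation initiation, 11 of 35 genes rose and 14 fell (11 and 15 adjusted over the list alone), with EIF4A2 up and EIF4G2, a scaffold of initiation, which fell by 0.61. SR genes had 11 up and 6 down of 45, hnRNPs 17 and 20 of 71 and the core spliceosome 24 and 20 of 94, the same counts adjusted over the list alone; DYRK1B (0.61), PRPF6 (0.51) and CELF6 (0.44) rose. Noradrenergic genes had 12 up and 10 down of 34, the same adjusted over the list alone, with CHGB (0.53) and GATA3 (0.47) up, while STMN2 fell by 0.40. Of 18 measured mesenchymal genes, 4 rose and 3 fell (2 and 2 adjusted over the list alone), such as TWIST1 (0.43) and DCN, which fell by 0.47. Microexon genes had 25 up and 13 down of 83 (25 and 13 adjusted over the list alone) and synapse genes 20 and 12 of 60 (20 and 13), with the vesicle fusion gene VAMP2 up (0.62). Neurite genes had 19 and 20 of 75 (19 and 20), with NEFM, a neurofilament gene, which fell by 0.56. Mitochondrial genes had 13 and 21 of 55 (16 and 23), apoptosis genes 5 and 12 of 39 (5 and 12), with BCL2L12, which fell by 0.84, and chromatin genes 25 and 26 of 102 (26 and 26). The values of TWIST1, NEFM and BCL2L12 rest on 1 exon event each.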

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

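Covariates in the list tests and intron events in place of exon events in the proxy were tried only after the data had been seen. Over all alternatives, 207 values of the main results stayed within 1.5 times, within the spread or on the same side of the threshold, against 50 that moved further, 7 that lost the call, 4 that gained one and 1 that turned. Of the values of named genes and events, 1457 kept their side, 248 lost the call, 7 gained one and 0 turned. No called event changed sign under any alternative. The sign is that of the difference of the group mean percents, so only leaving out a library could have changed it. Without the variance trend, 12 exons were called higher and 2 lower, 0 and 0 introns, 0 acceptor and 0 donor events. In that setting limma had 1295, 644, 396 and 314 sites at an unadjusted p below 0.05, the quasi-binomial test called 327, 166, 49 and 53, and 68 of the 69 named called events lost the call without the trend. The cause was not tested. At 15 points, by construction, fewer were called: 118 and 27 exons, 21 and 32 introns, 14 acceptor and 17 donor events, and 18 named events lost the call. With no size threshold, by construction, more were: 335 and 94 exons, 162 and 154 introns and 38 acceptor events, and 2080 and 2032 proxy genes. With it the list tests of events gave adjusted p = 0.0119 for polyamine metabolism, 0.0119 for SR proteins, 6.62e-04 for detained-intron genes, 0.0472 for noradrenergic identity and 6.62e-04 for hnRNPs, where the direction turned from fewer to more genes with a called event, while the microexon and synapse lists lost the call (0.221 and 0.136), as they did with covariates (0.193 and 0.176; the cause was not tested). On the percent scale, 23 introns were called higher and 40 lower, with 6 acceptor and 7 donor events, and 22 of the 69 named called events lost the call. With no filter on the mean percent, 43 introns were called lower, with 15 acceptor events, where more events were tested. A rule without a test called 16 and 29 introns. Balanced reads called 17 and 27, where fewer introns were tested. Mean retention differed by 0.297 points over introns of 5% to 95% and by 0 as a median, and mean microexon inclusion by 1.63 points at 3 to 15 nt and by 3.17 as a median. The proxy called 178 and 126 genes with a pseudocount of 0.1, 10 and 8 with 5 and 98 and 80 from the event with the most reads. With an estimated correlation, the lists of detained-intron genes (0.479), ribosomal proteins (0.259) and DNA repair (0.162) lost the call. The cause was not tested for the percent scale, the rule without a test, the means or the proxy.

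With each library left out in turn, 128 to 182 exons were called higher and 30 to 42 lower, 41 to 69 and 44 to 72 introns, 8 to 22 acceptor and 19 to 29 donor events, and 65 to 70 and 42 to 49 proxy genes. Counts moved over 1.5 times without Control replicate 1 (134 exons higher, 44 introns lower), Control replicate 2 (19 donor events), Control replicate 3 (132 and 30 exons), DFMO replicate 1 (128 and 30 exons, 41 introns higher, 8 acceptor events) and DFMO replicate 2 (15 acceptor and 20 donor events). The mean differences ran from 0.0703 to 0.131 points for retention and from 2.23 to 2.54 points for microexons. Of the 69 called events that the naming rule covers, 36 kept the call without each library in turn. A replicate block, offsets of 1 and 0.1, at least 20 reads, a score of OK or better, median-of-ratios scaling and leaving out low genes kept every count within 1.5 times. Thinning all libraries to the shallowest still called 199 exons higher and 51 lower.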

Other observations

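Tests of chance in the direction of donors, of donors that were not called, of sterol, NRF2 and ATF4 genes, of decay-linked exons, of microexons against longer exons and of other splits were chosen after the results were seen; those of depth, GC content, starting level, intron reads, unspliced RNA, host transcripts and called acceptors were chosen before.

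Called cassette exons were mostly higher with DFMO, 203 of 259 (78.4%), and 60.3% of tested exons were higher, against 44.5% to 56% over the other splits of the libraries. Each of those splits holds part of the difference between Control and DFMO, so their range is no measure of chance. Tables argue against depth, since thinning all libraries to the shallowest gave 79.6% (199 higher, 51 lower; 95% interval 74.1 to 84.4), and against a low starting level as the whole cause. The share was 93.3% at a Control mean under 30%, 78% at 30% to 70% (78 of 100; 68.6 to 85.7) and 69.7% above that (59.6 to 78.5), so it varied with the starting level. Exons near either end of the scale have more room to move away from it, which favors such a slope. Fewer called exons started under 30% (60) than over 70% (99). GC content stays open, since from the lowest to the highest GC tertile the share rose from 60.4% (32 of 53; 46 to 73.5) through 79.7% to 89.3% (92 of 103), and GC content was known for 76.7% of tested exons. DFMO itself may also shift exons to inclusion, a hypothesis that these libraries cannot part from GC content.

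Introns called higher were longer than those called lower, with medians of 3284.5 and 383 nt, a ratio of 8.58 (permutation p = 1e-05, the smallest that 100000 permutations can give). The permutation p values for introns take called introns as independent and do not measure the spread between libraries. The starting level, examined above for exons, was not examined for introns. Reads of other transcripts inside long introns are argued against for called introns with balanced reads (ratio 10.9). These were 17 of the 64 called higher and 27 of the 76 called lower, and for the rest the question stays open. Carry-over of unspliced RNA that raises introns of every length is argued against by introns under 500 nt. Of those, 41.2% (525 of 1273, 95% interval 38.5 to 44) were higher, against 62.9% of introns over 2000 nt. This does not cover carry-over that weighs mostly on long introns, which stays open. A change of the host transcript is argued against by genes with a proxy change under 0.2 on the log2 scale (ratio 7.12; 40 higher, 33 lower; permutation p = 2e-05). Length and difference had a Spearman correlation of 0.23, against -0.13 to 0.13 over the other splits of the libraries. That range has the same limit as the one for exons. An effect of DFMO that depends on intron length, as between HAND2-AS1 and HDAC9, may thus remain, as a hypothesis found and tested on the same data. The proxy of HDAC9 itself fell by 0.58 on the log2 scale (limma adjusted p = 1.3e-04), so a change of its host transcript is not argued against.

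Among called donor events, 21 of 32 moved to the form with the shorter exon (exact binomial p = 0.11), so chance in so few events could give this. A general gain of shorter forms stays open for called events, since 64% of the called acceptor events (16 of 25; exact binomial p = 0.23) moved that way too. Among events that were not called, donors moved to the shorter form in 855 cases and to the longer in 604 (58.6%; exact binomial p = 5.4e-11), while acceptors gave 986 and 996 (49.7%), which argues against a general gain. The binomial p takes events as independent and does not measure the spread between libraries. Over the other splits of the libraries, the share for tested donors ran from 45.2% to 56.9%, against 58.8% for the real split. That range, too, has the limit given for exons.

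ACAT2, MVD, MVK and FDFT1 were among 5 sterol genes that had fallen on the proxy, so those not yet seen were tested as a group. Of 18 measured, 13 fell, among them INSIG1 (-0.56), IDI1 (-0.55) and DHCR7 (-0.53), and TM7SF2 rose (camera adjusted p = 2.7e-05, and adjusted p = 0.0259 with an estimated correlation). The p values of the sterol, NRF2 and ATF4 lists were adjusted over those lists alone, apart from the 18 lists fixed before. This is a milder adjustment, and one over all lists together was not made. Whether the sterol list would pass it with an estimated correlation is therefore open. A lower output of sterol synthesis genes with DFMO may be general, with that limit. After NQO1, AKR1C3, NQO2, IDH1 and CBR1, 16 other NRF2 targets were tested, of which 9 fell, such as GCLM (-0.41), and 4 rose (adjusted p = 0.0716, and adjusted p = 0.323 with an estimated correlation), which leaves the question open. After ASNS rose, 30 other ATF4 targets gave 6 higher and 4 lower (adjusted p = 0.328, and adjusted p = 0.329 with an estimated correlation). Their median was 0.05 and the highest, ATF5, 0.31, so none rose as far as ASNS (0.59), and a small rise of the group stays open.

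Exons of decay-linked transcripts rose in the splicing factor genes SRRM2 (5.37% to 15.7%), SRSF11 (6.58% to 20.4%) and HNRNPA2B1 (54.7% to 69.0%). Such exons that were not called were higher in 17 of 28 cases (60.7%) against 59.7% of 7213 other exons (Fisher's exact p = 1), which leaves a general rise open. Microexons gained 0.93 points more than longer exons with exons permuted (permutation p = 0.0373), but those of 3 to 15 nt gained 0.16 points more (permutation p = 0.805), and over libraries the exact p of 0.1 is the smallest possible, so a larger gain of microexons stays open.

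The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In each case 1 split, the real one, gave a count as large. Every other split mixes Control and DFMO libraries in both groups, which adds the difference between them to the spread within groups. Low counts in those splits therefore do not give a rate of false calls. The shares and correlations given above for those splits likewise hold part of the difference between Control and DFMO. The real split called 259 exons, 140 introns, 25 acceptor events, 32 donor events, 104 proxy genes and 5 lists at the preset correlation, and the highest of the others 0, 1, 1, 1, 0 and 4.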
